A study of Xenopus laevis with 12 samples.

How the data were processed

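RNA from whole heads of control and thioridazine-treated Xenopus laevis tadpoles at NF stages 45 and 47 was sequenced in 12 libraries, 3 for each of the 4 groups of stage and treatment. Libraries were made with a TruSeq v2 kit, which does not keep the strand, and read as single-end 100 bp reads on an Illumina HiSeq instrument, per the labels' protocols. The deposited files hold raw read counts per gene, 1 file per library, with a numeric gene identifier and a whole number for each of 37018 genes. The submitters' processing notes name Trimmomatic, HISAT2, HTSeq and DESeq2. Their versions, the genome build, the annotation and the handling of reads that map to several places are not given in the sources used here. The files hold no lines for unassigned reads, and 3 of the 12 have Windows line ends, which were removed. Gene names came from a table of the assembly Xenopus_laevis_v10.1, which matched 33597 identifiers and left 3421 without a name. That table served for names alone, since the build behind the counts is not known from those sources, and no coordinates are given. The endings .L and .S mark the homeologs (the pair of copies from the species' genome duplication).

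Each library held between 11998636 and 16933777 counts and between 30733 and 31514 genes with a count. Spearman correlations between replicates of a group were 0.963 to 0.985, no pair of libraries was identical, and the mean chi-square per gene between replicates was 6.59 to 16.3, above the 1 that counting error alone gives. The first 4 principal components held 25.3, 18.8, 14.0 and 11.9% of the variance.

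Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit with robust spread, TMM scaling, filterByExpr), which tested 27050 genes with all 12 libraries in a single fit and a coefficient for each group. There were 5 contrasts: thioridazine against control at each stage, stage 47 against stage 45 in controls and in treated heads, and the difference between the treatment effects of both stages. P-values were adjusted by Benjamini and Hochberg within a contrast, and genes under 0.05 were called. Levels are CPM (counts scaled to the TMM-adjusted library size), and log2 CPM used a prior count of 2. The sum of a list is the sum of its members' CPM.

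The 38 gene lists, the contrasts, the tests and the rule for naming genes were set before the data were examined. The lists cover cartilage, bone, cranial crest, metalloproteinases, ADAM proteases, fibrous matrix, thyroid hormone, skeletal muscle, myogenic regulators, photoreceptors, lens, pigment cells, neurons, neural progenitors, receptors bound by phenothiazines, myeloid cells, complement and interferon, and DNA replication. They also cover heat shock and stress responses, immediate early genes, cholesterol synthesis, lysosome, xenobiotic metabolism, epidermis, cilia, inner ear, red blood cells, liver, pancreas and gut, heart, retinoic acid, signalling pathways, the circadian clock, ribosomal proteins, the respiratory chain, histones and glycolysis. The results of 1 further list and of 1 gene named under the rule are not reported here, though counts of lists include that list. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with p-values adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it.

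The named genes were, for each treatment contrast, the 10 raised and 10 lowered genes with the largest change among called genes with a name, a mean of at least 1 CPM in a group and no overlap between the groups (5 and 5 for the stage contrasts). Where under 10 genes passed, the 5 and 5 with the smallest p stood in and are said not to pass. From the 8 lists with the smallest p of each treatment contrast came up to 3 called members, or the member with the smallest p. The genes mmp1, mmp9, mmp11, mmp13, mmp14, thrb, klf9, dio3, thibz, col2a1, sox9 and drd2 were named whatever their values. Genes named under the comparison over both stages were chosen after their values were seen.

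Whether replicate numbers pair samples was checked by the correlation, across genes, of deviations from the group means between samples of the same number. Between control and treated samples it was 0.336, 0.586 and 0.326 at stage 45 and 0.18, 0.225 and 0.471 at stage 47, all above 0.1, so a fit with the number as a block stands beside each treatment contrast. Between stages it was 0.181, 0.014 and 0.352 in controls and 0.562, 0.04 and 0.087 in treated heads. All of these were positive and some lay above 0.1, so a number may be shared in part between stages. Tests that take pairs of different stages as independent rest on that assumption.

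The alternatives set beforehand were DESeq2 1.42.0, RLE and upper-quartile scaling, no filter on low counts, at least 1 CPM in at least 3 libraries, a fit of only the groups compared, a threshold of 2-fold, homeologs summed, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were a block for the replicate number within each stage, a fit without the library of lowest liver level in 3 of the groups, the lens list with 58 numbered gamma-crystallin copies, and the average treatment effect over both stages. For counts of genes and lists, every split of the libraries was also tested, or 30 drawn assignments for the difference between stages.

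The gene test was tested on simulated data for the stage 47 contrast, with counts drawn for 27050 genes. It recovered 15, 30, 43 and 47 of 50 genes changed 1.5-, 2-, 3- and 4-fold, with 9 false calls and 0 in the wrong direction. The list test was run on data simulated for stage 45, with the 24 pigment genes shifted by 0.5 on the log2 scale. It gave that list an adjusted p of 2.39e-18 (0.00147 with an estimated correlation) and called 0 of the 37 others. Counts were drawn independently for each gene and without pairing of samples. These values thus do not show how often the tests call falsely where genes are correlated.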

Results

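Transcript levels were measured by RNA sequencing in whole heads of Xenopus laevis (African clawed frog) tadpoles, as read counts per gene. Thioridazine is a phenothiazine antipsychotic drug that blocks dopamine receptors. Per the labels' protocols, embryos were kept in 90 µM thioridazine at 18 °C during neurula stages 14 to 26 of the Nieuwkoop and Faber (NF) series, and the treated heads came from tadpoles with malformed faces. Control and treated heads were taken at NF stages 45 and 47, with 3 libraries in each of the 4 groups. A library held between 11998636 and 16933777 counts. The group means were 13847355 (control, stage 45), 14933701 (thioridazine, stage 45), 15354467 (control, stage 47) and 12994911 (thioridazine, stage 47). The replicates are labelled biological replicates without saying which clutch or how many animals they hold, so p-values measure the spread between these samples. Levels are scaled counts (CPM, mean ± SD, n = 3 per group), and the median standard error (SE) of a log2 fold change between thioridazine and control was 0.18 at each stage. The crystallin genes named here belong to a family of near-identical copies, which makes the level of any single copy uncertain.

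At stage 45, the question was which transcripts differ in malformed heads at the earlier stage. As gene lists, pigment cell transcripts were higher in treated than in control heads, and those of lens, skeletal muscle and neurons were lower, while no single gene passed the threshold. The lens, muscle and neuron calls were lost with an estimated correlation between genes (adjusted p = 0.162, 0.299 and 0.258). The 24 pigment cell genes summed to 1234 ± 84.6 CPM in treated heads against 856 ± 53 CPM in controls. The 27 lens genes summed to 1242 ± 106 CPM against 2170 ± 635 CPM, and the 79 skeletal muscle genes to 14500 ± 1610 CPM against 18900 ± 3690 CPM.

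The gene test (edgeR) called 0 of 27050 genes at stage 45, with 1441 genes at an unadjusted p under 0.05 (609 higher, 832 lower) where 1352 would be expected by chance. DESeq2 called 76 genes (35 higher, 41 lower). The replicate numbers paired treated and control samples at both stages. With the number as a block 16 genes passed (10 higher, 6 lower), and with a block within each stage, chosen after the data were seen, 268 passed (110 higher, 158 lower). Leaving out 1 library gave at most 9 genes, without control replicate 3 of stage 45, and 1 gene each without control replicate 2 of stage 45 or control replicate 2 of stage 47.

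The higher genes with the smallest p at stage 45, none of which passed, were mostly genes of pigment cells. The level of ednrb2.S (gene 379394), an endothelin receptor of the pigment cell lineage, was 52.7 ± 7.43 CPM in treated heads against 29.9 ± 2.65 CPM in controls, with an adjusted p of 0.139 and 7.49e-05 with the block within each stage. Dopachrome tautomerase (dct.L, gene 100381161), an enzyme of melanin synthesis, stood at 50.1 ± 2.94 CPM against 26.2 ± 4.9 CPM, with a log2 fold change of 0.94 (SE 0.15, adjusted p = 0.139, with the block within each stage 0.000188). The melanosome protein mlana.L (gene 108714207) was 2.24-fold higher (21.6 ± 5.02 against 9.68 ± 1.79 CPM, adjusted p = 0.233, with that block 0.000182). The melanosome ion exchanger slc24a5.L (gene 108711395) measured 16.9 ± 2.05 against 8.72 ± 1.91 CPM (adjusted p = 0.233, with that block 0.00115). The cytokine signalling inhibitor cish.S (gene 108715831) was 2.51-fold higher, at 11.3 ± 1.19 against 4.52 ± 1.31 CPM (adjusted p = 0.233, with that block 0.0011).

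The lower genes with the smallest p at stage 45, which also did not pass, were all gamma-crystallins of the lens. The most abundant, crygdl.13.S (gene 108704739), measured 509 ± 32.3 CPM in treated heads against 980 ± 187 CPM in controls (log2 fold change -0.95, SE 0.18, adjusted p = 0.233). The copy crygbl.5.S (gene 108704904) stood at 19.1 ± 1.73 against 42.8 ± 7.26 CPM with an adjusted p of 0.139. For crygbl.3.S (gene 108704903), crygbl.2.S (gene 108704910) and crygdl.11.L (gene 108696687) the log2 fold changes were -1.27, -1.02 and -0.79, each with an adjusted p of 0.233. With the block within each stage the adjusted p was 0.000805 for crygbl.3.S and 0.0194 for crygdl.11.L. It stayed over 0.05 for crygdl.13.S (0.0546), crygbl.5.S (0.0918) and crygbl.2.S (0.195). At stage 47, crygbl.5.S measured 29.7 ± 3.55 CPM in treated and 27.5 ± 6.15 CPM in control heads.

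Of 38 gene lists fixed before the data were examined, 14 passed at stage 45 with a preset correlation between genes (9 higher, 5 lower), and of the lists reported here the pigment cell list passed also with an estimated correlation. Among pigment cell genes 21 of 24 were higher (median log2 fold change 0.32, adjusted p = 8.26e-11), with an adjusted p of 0.0219 with an estimated correlation, and 10 members passed when adjusted over the list alone. With the replicate block its adjusted p with an estimated correlation was 0.104, and with the block within each stage 0.242. Of the lens genes 25 of 27 were lower (median -0.57, adjusted p = 2.49e-12), 11 of them passing when adjusted over the list alone, and the adjusted p was 0.162 with an estimated correlation. The lens filament gene bfsp2.L (gene 108718497), which is no crystallin, measured 4.7 ± 0.344 CPM against 10.1 ± 3.34 CPM (adjusted p = 0.315, with the block within each stage 0.00728).

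Skeletal muscle transcripts were lower in 67 of 79 genes at stage 45 (median -0.29, adjusted p = 2.19e-16, and 0.299 with an estimated correlation), 6 of them passing when adjusted over the list alone. Among them the fast-fibre actinin actn3.L (gene 446326) measured 182 ± 11 CPM against 265 ± 27 CPM (adjusted p = 0.319, with the block within each stage 0.018). Genes of neurons and synapses were lower in 77 of 85 (median -0.21, adjusted p = 2.99e-13, and 0.258 with an estimated correlation). Among these the neurofilament gene nefh.L (gene 108715402) stood at 8.09 ± 0.733 against 13.4 ± 0.723 CPM (adjusted p = 0.354, with that block 0.00987). Inner ear, olfactory and lateral line genes were lower in 28 of 40 (median -0.13, adjusted p = 0.00181, and 0.136 with an estimated correlation). Glycolysis and hypoxia genes were lower in 46 of 64 (median -0.12, adjusted p = 0.00151, and 0.258 with an estimated correlation).

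The other lists reported here as higher at stage 45 lost their call with an estimated correlation, where their adjusted p lay between 0.258 and 0.798. Genes of DNA replication and mitosis were higher in 90 members and lower in 11 (median 0.17, adjusted p = 1.6e-09), with cyclin A2 (ccna2.L, gene 734775) at 37.0 ± 6.3 against 27.4 ± 2.16 CPM. Lysosome genes were higher in 59 of 71 (median 0.15, adjusted p = 3.4e-09). The lysosomal hexosaminidase hexb.L (gene 100158266) measured 89.7 ± 5.04 against 62.1 ± 9.72 CPM (adjusted p = 0.413, with the block within each stage 0.00987). Epidermal genes were higher in 64 of 80 (median 0.16, adjusted p = 2.34e-07), among them the desmosome gene pkp3.S (gene 403375) at 98.7 ± 7.18 against 74.1 ± 9.35 CPM. Myeloid genes were higher in 51 of 62 (median 0.20, adjusted p = 4.99e-06), among them the receptor adaptor tyrobp.L (gene 108696884) at 4.74 ± 0.917 against 2.91 ± 0.221 CPM. None of ccna2.L, hexb.L, pkp3.S and tyrobp.L passed on its own in edgeR without a block. With the block within each stage pkp3.S passed too (adjusted p = 0.0194), while ccna2.L (0.0578) and tyrobp.L (0.0899) did not. Ribosomal protein genes (127 of 131 higher, median 0.10, adjusted p = 1.1e-05), xenobiotic and oxidative stress genes (61 of 72, median 0.16, adjusted p = 3.06e-05) and retinoic acid pathway genes (32 of 42, median 0.09, adjusted p = 0.0102) were higher too. The ribosomal call was lost, with its direction turned, without control replicate 1 (adjusted p = 0.201), and lost without thioridazine replicate 2 (0.366), the xenobiotic call without control replicate 1 (0.121), and the retinoic acid call without thioridazine replicate 1 (0.187), all of stage 45.

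**Figure D1:**
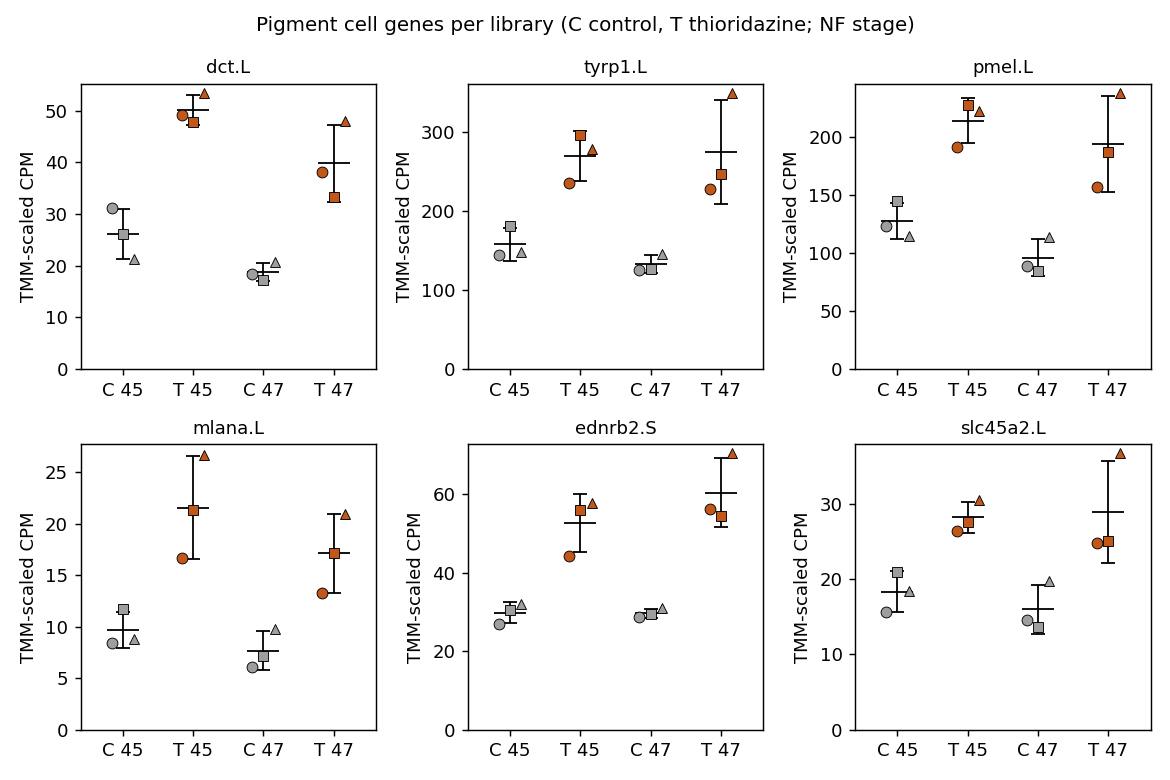
Levels of pigment cell genes in CPM for each library of the 4 groups (circle, square and triangle for replicates 1, 2 and 3, grey for control and orange for thioridazine, bars for mean ± SD). The dct.L level was 50.1 CPM in treated and 26.2 CPM in control heads at stage 45, and 39.8 against 18.7 CPM at stage 47.

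At stage 47, the question was which transcripts differ in malformed heads at the later stage. The gene test called 20 genes, all of which rose, and pigment cell genes, a cone photoreceptor kinase and an epithelial regulator were among them. Pigment cell genes summed to 1219 ± 171 CPM in treated heads against 802 ± 49.5 CPM in controls. The liver genes summed to 2407 ± 966 CPM against 4354 ± 939 CPM, with a ratio of treated to control of 0.553 at stage 47 and 1.42 at stage 45. Within a group, the highest library held between 1.52 and 2.68 times the liver level of the lowest. The mean log2 difference over liver genes, thioridazine minus control of the same replicate number, varied far more. For replicates 1, 2 and 3 it was 3.016, 0.069 and -1.965 at stage 45, and -0.247, -3.616 and -1.157 at stage 47.

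Of the 20 genes, 15 were at least 2-fold higher and 11 have a gene name. DESeq2 called 68 genes at stage 47 (64 higher, 4 lower), the replicate block 51 (all higher) and the block within each stage 171 (138 higher, 33 lower), and each of these held all 20. At an unadjusted p under 0.05 there were 953 genes, fewer than the 1352 expected by chance. The count was 0, 2 and 1 without control replicates 1, 2 and 3 of stage 47, and 12, 6 and 11 without thioridazine replicates 1, 2 and 3 of stage 47. It was 7 without the library of lowest liver level in 3 of the groups, an alternative chosen after the data were seen.

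Pigment cell genes made up 4 of the 10 named genes with the largest changes at stage 47, 3 of them members of the pigment list. The endothelin receptor ednrb2.S rose from 29.7 ± 1.18 to 60.4 ± 8.8 CPM (log2 fold change 1.02, SE 0.13, adjusted p = 0.00865). The melanin enzyme dct.L rose 2.13-fold to 39.8 ± 7.46 CPM (adjusted p = 0.0149). Its relative tyrp1.L (gene 380184) rose from 133 ± 11.6 to 275 ± 65.8 CPM (adjusted p = 0.0199). The melanosome matrix protein pmel.L (gene 734169) rose from 95.8 ± 15.8 to 194 ± 41.2 CPM (log2 fold change 1.01, SE 0.16, adjusted p = 0.0242), and its adjusted p was 0.0905 when only the stage 47 groups were fitted. Without control replicate 1 of stage 47 the adjusted p was 0.0551 for ednrb2.S, 0.0919 for dct.L, 0.165 for tyrp1.L and 0.207 for pmel.L. The pigment list as a whole was higher in 18 of 24 genes (median 0.34, adjusted p = 1.92e-13, and 0.00499 with an estimated correlation), with 9 members passing when adjusted over the list alone. With an estimated correlation its adjusted p was 0.0621 with the replicate block and 0.187 with the block within each stage.

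Outside the pigment cells, the cone opsin kinase grk7.L (gene 100192358) rose 2.21-fold at stage 47, from 19.7 ± 2.91 to 43.5 ± 3.18 CPM (adjusted p = 0.00694). The epithelial transcription factor genes elf3.S (gene 108709471) and elf3.L (gene 108708141) rose from 60.2 ± 5.79 to 120 ± 18.7 CPM and from 25.7 ± 3.21 to 48.2 ± 7.52 CPM (adjusted p = 0.00865 and 0.0329). The NADPH oxidase organizer gene noxo1.1.L (gene 108701677) had the largest fold change of the called named genes, 8.35-fold, from 0.843 ± 0.552 to 7.35 ± 0.672 CPM (adjusted p = 0.0242). The serine protease gene tmprss2.3.L (gene 397830) rose 3.15-fold to 10.3 ± 2.63 CPM (adjusted p = 0.0286). The gene gatd3alc.2.L (gene 108698348) rose 2.53-fold to 23.7 ± 5.22 CPM (adjusted p = 0.0149). Each of these calls was lost without control replicate 1 of stage 47, where the adjusted p was 0.0551 for grk7.L and elf3.S, 0.235 for elf3.L, 0.146 for noxo1.1.L and tmprss2.3.L, and 0.0879 for gatd3alc.2.L. Without control replicate 2 or 3 of stage 47, grk7.L alone of the 10 named genes stayed called.

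As lists at stage 47, 22 of 38 passed (13 higher, 9 lower). Of the lists reported here, pigment cells passed also with an estimated correlation. Liver genes were lower in 61 of 67 (median -1.39, adjusted p = 3.95e-20, and 0.354 with an estimated correlation). The apolipoprotein gene apoa4.S (gene 399000), the liver gene with the smallest p, measured 0.298 ± 0.197 against 1.57 ± 0.571 CPM. It did not pass (adjusted p = 0.594, with the block within each stage 0.0611).

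Photoreceptor and retinal pigment epithelium genes were higher in 70 of 79 at stage 47 (median 0.27, adjusted p = 1.87e-17, and 0.354 with an estimated correlation), with 13 passing when adjusted over the list alone. Their sum was 4571 CPM in control replicate 2 of stage 47, against 7003 and 6985 CPM in control replicates 1 and 3. In treated replicates 1, 2 and 3 of that stage it was 7324, 7706 and 7185 CPM, so the difference in the sum leaned on 1 control library. The list call with the preset correlation held without that library. The mean log2 shift of the list in pairs 1, 2 and 3 was 0.249, 0.651 and 0.116. Lens genes were higher in 21 of 27 (median 0.30, adjusted p = 4.49e-05, and 0.354 with an estimated correlation), a call lost without control replicate 2 of stage 47 (0.101). Neural progenitor genes were higher in 53 of 67 (median 0.13, adjusted p = 3.34e-08, and 0.354 with an estimated correlation). The neurogenesis factor neurod4.S (gene 108709887) among them stood at 10.6 ± 1.14 against 6.38 ± 0.791 CPM (adjusted p = 0.171, with the block within each stage 0.0136). Lysosome genes (59 of 71, median 0.14, adjusted p = 6.35e-10) and myeloid genes (54 of 62, median 0.24, adjusted p = 2.27e-08) were higher, each with an adjusted p of 0.234 with an estimated correlation. The lysosomal galactosidase gla.S (gene 734749) measured 27.2 ± 2.26 against 18.1 ± 2.32 CPM (adjusted p = 0.48, with that block 0.0125). The level of tyrobp.L was 6.65 ± 0.49 CPM in treated heads (log2 fold change 0.73, adjusted p = 0.521, with that block 0.0732).

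Skeletal muscle genes were lower in 67 of 79 at stage 47 (median -0.15, adjusted p = 1.59e-06), a call lost with an estimated correlation (0.463) and without control replicate 1 of stage 47 (0.0804). The slow troponin tnnt1.S (gene 444636) measured 1.91 ± 0.398 against 3.43 ± 0.326 CPM and did not pass, nor did it with the block within each stage (adjusted p = 0.145). Neuronal genes were lower in 69 of 85 (median -0.14, adjusted p = 1.76e-06, and 0.387 with an estimated correlation). Heart genes (31 of 38 lower, median -0.15, adjusted p = 7.14e-05) and red blood cell genes (32 of 39 lower, median -0.19, adjusted p = 0.000812) were lower, each with an adjusted p of 0.354 with an estimated correlation. Respiratory chain genes were lower in 111 of 128 (median -0.07, adjusted p = 0.00087, and 0.838 with an estimated correlation), a call lost without control replicate 1 (0.746) or thioridazine replicate 1 (0.557) of stage 47. Pancreas and gut genes were lower in 17 of 21 (median -0.22, adjusted p = 0.00128, and 0.354 with an estimated correlation), a call lost without control replicate 3 of stage 47 (0.212).

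The other list calls of stage 47 reported here did not hold with an estimated correlation, where their adjusted p lay between 0.234 and 0.863, and each was lost without at least 1 library of stage 47. Matrix metalloproteinase genes were higher in 24 of 30 (median 0.12, adjusted p = 0.00185, without thioridazine replicate 1 0.306). Cranial neural crest and pharyngeal arch regulators were higher in 52 of 77 (median 0.07, adjusted p = 0.00244, without control replicate 2 0.663). Bone genes were higher in 17 of 25 (median 0.12, adjusted p = 0.00993, without thioridazine replicate 1 0.244 and without control replicate 3 0.0626). Genes of the Wnt, BMP, FGF, Hedgehog and Notch pathways were higher in 103 of 150 (median 0.08, adjusted p = 0.00993, without control replicate 2 0.193 and without thioridazine replicate 1 0.178). Immediate early genes were higher in 38 of 51 (median 0.12, adjusted p = 0.000297, without control replicate 2 0.437 and without thioridazine replicate 2 0.0549). Ribosomal protein genes were higher in 118 of 131 (median 0.06, adjusted p = 0.0379), and lost the call without control replicate 2 (0.301), thioridazine replicate 2 (0.0838) or, with its direction turned, thioridazine replicate 3 (0.168). Complement and interferon genes were lower in 26 of 49 (median -0.11, adjusted p = 0.0379), a call lost with the replicate block (0.0702) and with the block within each stage (0.111). That call was also lost without control replicate 1 (0.131) or 2 (0.117) and without thioridazine replicate 2 (0.127) or 3 (0.208). Heat shock and stress response genes were lower in 55 of 87 (median -0.06, adjusted p = 0.0436), and their adjusted p was over 0.05 without 9 of the 12 libraries, up to 0.339 without control replicate 2 of stage 47.

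**Figure D2:**
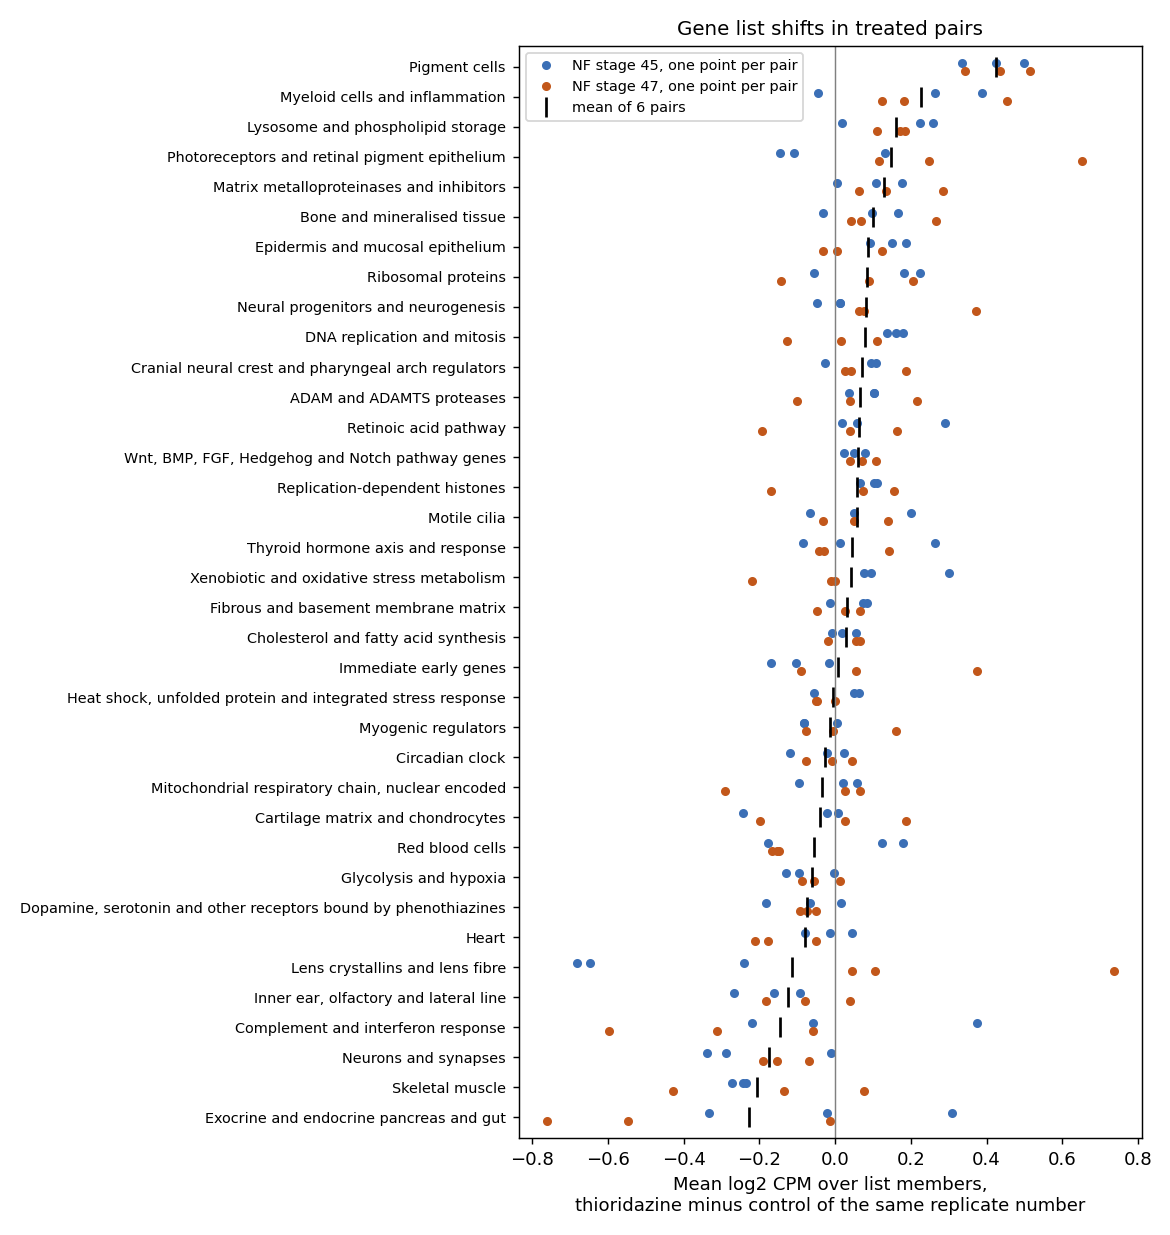
Mean log2 difference between thioridazine and control libraries of the same replicate number for 36 gene lists (blue for the 3 pairs of stage 45, orange for the 3 pairs of stage 47, black tick for the mean of all 6). Pigment cells lay highest, with a mean of 0.42 over the 6 pairs. The liver list, whose pairs ranged from -3.616 to 3.016, is not shown.

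With both stages in 1 comparison (6 treated against 6 control libraries, a comparison chosen after the data were seen), 39 genes passed, 37 higher and 2 lower, and 599 passed with the block within each stage (330 higher, 269 lower), among them all 39. The list test gave pigment cells an adjusted p of 8.93e-15, and 0.00344 with an estimated correlation, a call that the block within each stage lost with an estimated correlation (0.156). Genes named next were chosen after their values were seen. Higher in 6 of 6 pairs were ednrb2.S (log2 fold change 0.92, SE 0.09, adjusted p = 0.00127), dct.L (1.01, SE 0.11, adjusted p = 0.00157), grk7.L (0.80, SE 0.09, adjusted p = 0.00167) and mlana.L (1.15, SE 0.16, adjusted p = 0.00823). The prolactin gene prl.2.S (gene 108697263) was higher in 6 of 6 pairs as well (1.18, SE 0.17, adjusted p = 0.00889), and so was cish.S (1.10, SE 0.17, adjusted p = 0.016), whose product inhibits signalling by prolactin receptors. The genes that fell were both homeologs of the transcriptional repressor bcl6. Their log2 fold changes were -0.58 for bcl6.L (gene 495412, SE 0.10, adjusted p = 0.043) and -0.54 for bcl6.S (gene 446862, SE 0.10, adjusted p = 0.0499), lower in 6 of 6 pairs.

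Across genes, the treatment effects at the 2 stages had a Pearson correlation of 0.15 and a Spearman correlation of 0.242 over 27050 genes, which are not independent replicates. No gene was called at both stages by edgeR, and 17 genes were called at both by DESeq2, all higher, where 0.152 would be expected if genes were independent. Of the 20 genes called at stage 47, 18 had the same sign at stage 45. With the block within each stage 44 genes were called at both stages (37 higher and 7 lower at both), where 1.69 would be expected if genes were independent, which they are not. Of 200 assignments of the treatment labels, 51 gave a correlation between the treatment effects of the stages at least as large as the real 0.144 (exact p = 0.255), and 10 of 32 did within pairs (exact p = 0.312).

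The test of the difference between the stages called 0 genes (edgeR), with 575 at an unadjusted p under 0.05 where 1352 would be expected by chance. DESeq2 called 4 genes and the block within each stage 27 (25 higher, 2 lower). As lists, 11 of 38 passed, and none held with an estimated correlation. Lens genes differed most by the list test, with a median difference of 0.99 (adjusted p = 3.13e-20, and 0.168 with an estimated correlation) and 14 members passing when adjusted over the list alone. The difference had a median of -1.99 for liver genes (adjusted p = 7.42e-19, and 0.52 with an estimated correlation) and 0.39 for photoreceptor genes (adjusted p = 7.41e-18, and 0.52 with an estimated correlation). For the pigment list it was 0.02 (adjusted p = 0.704). Ribosomal protein genes had an adjusted p of 0.0712 for the difference, 0.0408 with the replicate block and 0.0252 with the block within each stage, and cartilage genes one of 0.113, and 0.0387 with the replicate block. With an estimated correlation these blocked calls were lost (0.887 and 0.879 for ribosomal protein genes, 0.851 for cartilage).

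**Figure D3:**
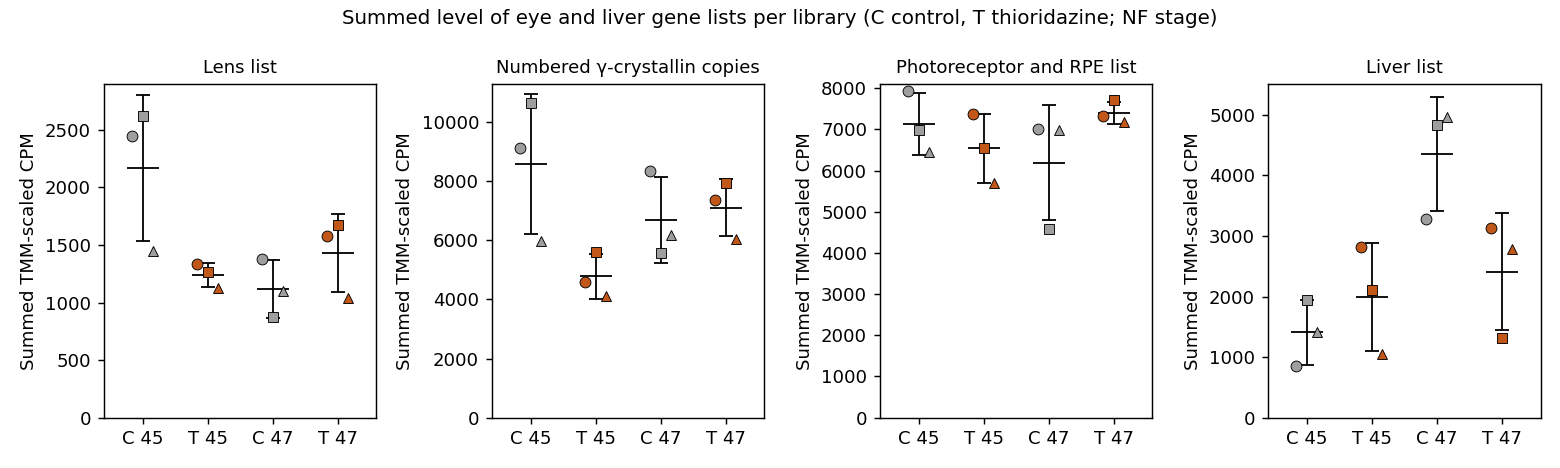
Summed CPM of gene lists for eye tissues and liver in each library of the 4 groups (circle, square and triangle for replicates 1, 2 and 3, grey for control and orange for thioridazine, bars for mean ± SD). Lens genes stood at 1242 CPM in treated and 2170 CPM in control heads at stage 45, and at 1431 and 1116 CPM at stage 47.

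Genes of matrix remodelling, the thyroid hormone axis, cartilage and the dopamine receptor were named beforehand because they bear on reshaping of the face and on the drug's target, and none passed between thioridazine and control at either stage in edgeR. The stromelysin-3 and collagenase genes mmp11.S, mmp11.L and mmp13.S had log2 fold changes of 0.63, 0.43 and 0.67 at stage 45 and of 0.73, 0.43 and 0.44 at stage 47. The collagenase gene mmp13.S measured 4.59 ± 1.21 against 2.9 ± 0.745 CPM at stage 45 (adjusted p = 0.819, with the block within each stage 0.08). At stage 47 it measured 12.6 ± 2.03 against 9.3 ± 2.19 CPM (with that block adjusted p = 0.216). The gelatinase gene mmp9.1.S stood at 56.6 ± 21.9 against 39.0 ± 4.92 CPM at stage 45 and 76.2 ± 26.3 against 72.1 ± 22.4 CPM at stage 47, and mmp9.2.L had log2 fold changes of 0.16 and 0.66. For mmp1.S they were 0.28 and 0.55, and for the membrane-bound mmp14.L 0.09 and 0.22. The thyroid hormone deiodinase gene dio3.L measured 20.3 ± 3.54 against 15.3 ± 1.24 CPM at stage 45 and 25.5 ± 3.11 against 17.9 ± 4 CPM at stage 47. Its adjusted p was 0.859 and 0.955, and 0.0959 and 0.0272 with the block within each stage. The hormone receptor gene thrb.S had log2 fold changes of 0.09 and 0.53, and its target klf9.L of 0.62 and 0.33.

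None of the cartilage genes named beforehand passed. The cartilage collagen col2a1.L measured 824 ± 72.1 CPM in treated and 810 ± 125 CPM in control heads at stage 45, and 581 ± 82.1 and 625 ± 163 CPM at stage 47. Its homeolog col2a1.S had log2 fold changes of -0.13 and -0.14, and the cartilage regulator sox9.S of -0.08 and 0.15. Its homeolog sox9.L measured 63.8 CPM in both groups at stage 45 and had a log2 fold change of 0.29 at stage 47. The dopamine receptor genes drd2.L and drd2.S had -0.17 and -0.09 at stage 45 and 0.19 and -0.20 at stage 47. Too few counts for a test, between 12 and 83 over all 12 libraries, fell on mmp1.L, mmp9.2.S, thrb.L, dio3.S, thibz.L and thibz.S.

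Of the lists that passed at neither stage between thioridazine and control, the 68 cartilage genes had a median of -0.06 (adjusted p = 0.139) at stage 45 and 0.05 (0.574) at stage 47. At stage 45 the cartilage list passed with the replicate block (adjusted p = 0.0438, and 0.692 with that block and an estimated correlation), and also without control replicate 2 (0.00792), thioridazine replicate 1 (0.00766) or thioridazine replicate 3 (0.00168) of stage 45. At stage 47 it passed without control replicate 3 (0.0223) or thioridazine replicate 2 (0.0479) of stage 47. Thyroid hormone genes were higher in 19 and lower in 19 of 38 at stage 45 (adjusted p = 0.637, and 0.686 at stage 47), with a median of -0.004 and a mean of 0.024 at stage 45. At stage 47 xenobiotic genes (adjusted p = 0.57) likewise differed in sign between a median of 0.03 and a mean of -0.07, and epidermal genes (adjusted p = 0.546) between -0.003 and 0.037. The adjusted p at stages 45 and 47 was 0.0819 and 0.233 for dopamine and other receptors, 0.0726 and 0.574 for fibrous matrix, 0.344 and 0.399 for ADAM proteases, and 0.18 and 0.68 for myogenic regulators. It was 0.229 and 0.127 for motile cilia, 0.298 and 0.574 for the circadian clock, 0.639 and 0.507 for cholesterol synthesis, and 0.296 and 0.451 for histones. Several of these passed without 1 library of the same stage. At stage 45 motile cilia did without control replicate 2 (0.0405) and without thioridazine replicate 1 (0.00205), 3 (0.0188) or, with the direction turned, 2 (0.026). So did histones without thioridazine replicate 1 (0.0431), receptors without control replicate 2 (0.0297), fibrous matrix without control replicate 3 (0.00116) or thioridazine replicate 2 (0.0123), and ADAM proteases without control replicate 1 (0.0366) or thioridazine replicate 2 (0.00066). At stage 47 motile cilia passed without thioridazine replicate 1 (0.000461), and cholesterol synthesis (0.0145) and histones (0.0297) without thioridazine replicate 2.

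Between stages 45 and 47 in control heads, the question was which transcripts change as the head grows. Liver, skin and immune transcripts rose, and those of lens, cartilage and the cranial crest fell. None of these list calls held with an estimated correlation (adjusted p = 0.268, 0.174 and 0.174 for liver, epidermis and myeloid cells, and 0.232, 0.47 and 0.174 for lens, cartilage and crest). With fry the adjusted p was 0.0433, 0.00718 and 0.00718 for liver, epidermis and myeloid cells. It was 0.0195 for lens, 0.141 for cartilage, which did not pass, and 0.00718 for crest. The gene test called 1689 genes, 820 higher and 869 lower at stage 47, where upper-quartile scaling gave 999 higher and 782 lower and the DESeq2 size factors 846 and 738. Of the 1689, 245 changed at least 2-fold (182 higher, 63 lower). The count was 429 and 443 without control replicates 1 and 2 of stage 47, and 861 and 735 without control replicates 1 and 3 of stage 45. All 67 liver genes were higher (median 2.24, adjusted p = 2.03e-19, and 0.268 with an estimated correlation), 12 of them called. The angiotensinogen gene agt.L (gene 108716126) rose from 0.453 ± 0.218 to 4.44 ± 1.35 CPM (log2 fold change 3.29, SE 0.62, adjusted p = 0.0103), and transferrin (tf.S, gene 379502) from 2.43 ± 1.82 to 21.9 ± 11.6 CPM (adjusted p = 0.0412). The plasma protein genes ptx.S (gene 398040) and f9.L (gene 108698922), a pentraxin and clotting factor IX, rose by 3.08 and 3.04 on the log2 scale, and apoa4.S from 0.107 ± 0.0927 to 1.57 ± 0.571 CPM (adjusted p = 0.0119).

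Among the genes that fell most in controls, the epidermal protease xepsin.S (gene 779376) fell from 13.2 ± 3.51 to 1.28 ± 0.636 CPM (log2 fold change -3.33, SE 0.32, adjusted p = 0.000381), and the keratin gene krt12.4.S (gene 379143) by 2.98 on the log2 scale from 31.7 ± 9.44 CPM (adjusted p = 0.0219). The astacin proteases astl3b.1.L (gene 108699323) and astl2e.2.L (gene 494813) had adjusted p of 0.0077 and 0.0075, with astl3b.1.L at 2.36 ± 0.892 and 0.138 ± 0.239 CPM. The actin regulator gene wasll.L (gene 108714569) fell by 2.35 on the log2 scale. The epidermis list was higher in 73 of 80 genes, 27 called (median 0.39, adjusted p = 1.09e-15, and 0.174 with an estimated correlation), and the myeloid list in 57 of 62 (median 0.54, adjusted p = 5.35e-12). Cranial crest regulators were lower in 64 of 77 (median -0.29, adjusted p = 4.68e-09), lens genes in 23 of 27 (median -0.88, adjusted p = 6.12e-08) and cartilage genes in 53 of 68 (median -0.35, adjusted p = 5.75e-06). Thyroid hormone genes were higher in 31 of 38 (median 0.25, adjusted p = 0.00058, and 0.0507 without control replicate 2 of stage 45). In all, 24 lists passed (16 higher, 8 lower), and with an estimated correlation 0 did.

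Between stages 45 and 47 in treated heads, epidermal, myeloid and immediate early transcripts rose, and those of DNA replication and of the cranial crest fell. None of these list calls held with an estimated correlation (adjusted p = 0.238, 0.165 and 0.186 for epidermis, myeloid and immediate early genes, and 0.238 for DNA replication and for the crest). With fry the adjusted p was 0.0355, 0.00932 and 0.00932 for epidermis, myeloid and immediate early genes. It was 0.0318 for DNA replication and 0.0161 for the crest. The gene test called 1314 genes, 565 higher and 749 lower, where upper-quartile scaling gave 794 higher and 635 lower and the DESeq2 size factors 580 and 621. Of the 1314, 187 changed at least 2-fold (159 higher, 28 lower). The count was 671, 748 and 428 without thioridazine replicates 1, 2 and 3 of stage 45, and 392, 442 and 506 without those of stage 47. The keratin-related larval skin genes ouro2.L (gene 100310818) and ouro1.S (gene 108709995) rose by 2.98 and 2.68 on the log2 scale (SE 0.37 and 0.24, adjusted p = 0.00366 and 0.000474), ouro2.L from 12.9 ± 4.87 to 102 ± 17 CPM. Their relative ouro1.L (gene 100310817), the matrix gene tnn.L (gene 108714346) and the sulfotransferase gene chst9l.3.S (gene 108700626) rose by 2.31, 2.18 and 3.40 on the log2 scale. In controls the log2 fold changes were 2.27 for ouro2.L (adjusted p = 0.00872) and 2.02 for ouro1.S (adjusted p = 0.0016).

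In treated heads xepsin.S fell from 6.36 ± 0.484 to 1.02 ± 0.39 CPM (adjusted p = 0.00161), krt12.4.S from 96.7 ± 43 to 9.5 ± 7.33 CPM (adjusted p = 0.0135), and astl2e.2.L by 2.77 on the log2 scale. The level of astl3b.1.L was 1.29 ± 0.239 at stage 45 and 0.028 ± 0.0485 CPM at stage 47 (adjusted p = 0.0125). The myosin gene myh8.L (gene 399414) fell from 12.1 ± 3.61 to 3.65 ± 0.697 CPM (log2 fold change -1.71, SE 0.29, adjusted p = 0.00656), where controls gave -0.86 (adjusted p = 0.0854). Genes of DNA replication were lower in 98 members and higher in 3, with 19 called lower (median -0.38, adjusted p = 1.33e-17, and 0.238 with an estimated correlation). Myeloid genes were higher in 58 of 62 (median 0.52, adjusted p = 8.43e-14) and immediate early genes had a median of 0.44 (adjusted p = 1.32e-13). Metalloproteinase genes had a median of 0.19 (adjusted p = 0.000124), cartilage genes -0.31 (0.000617) and liver genes 0.32 (0.0138). The liver call was lost without thioridazine replicate 1 (0.478) or 3 (0.269) of stage 47 and, with its direction turned, without thioridazine replicate 3 of stage 45 (0.782), and the cartilage call without the libraries of lowest liver level (0.245). In all, 15 lists passed (12 higher, 3 lower), and with an estimated correlation 0 did.

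The design also asks whether treated heads sit earlier or later along the change between stages. Over the 1689 genes called between stages in controls, the treatment effect at stage 45 and the stage effect had a Spearman correlation of 0.468, where simulated data without a treatment effect gave a mean of 0.473 (0.449 to 0.516 in 10 runs) from the shared libraries alone. Over the 1314 genes called in treated heads, the treatment effect at stage 47 and the stage effect gave 0.317, against a simulated mean of 0.487 (0.457 to 0.512). The simulated data hold no pairing between samples, so neither value was read as a departure from them. Over 4826 genes called for the mean stage effect, 2 of 20 assignments of the treatment labels gave a correlation as large as the real 0.328 at stage 45, and 9 of 20 one as large as the real 0.188 at stage 47. Genes are not independent replicates, and without the 3 libraries of lowest liver level the 0.317 was 0.206.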

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

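The tests of the pigment, lens and liver patterns, the block within each stage and the average over both stages were chosen after the results were seen, and the counts over splits of the libraries were set before those counts were seen.

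The treatment effect on 11 gene lists differed between stage 45 and stage 47 by the test of the difference itself (camera, preset correlation). The median difference in log2 fold change, stage 47 minus stage 45, was 0.987 for lens, 0.392 for photoreceptors and -1.986 for liver. It was 0.163 for immediate early genes (adjusted p = 2.58e-06) and 0.162 for neural progenitors (2.74e-06). For red blood cells it was -0.278 (adjusted p = 0.000373). With an estimated correlation none of the 11 held, the lowest adjusted p being 0.168 for lens. In 5 lists the call rested on single libraries. DNA replication (-0.168, adjusted p = 1.1e-07), xenobiotic metabolism (-0.128, 4.5e-05) and epidermis (-0.161, 0.000357) lost it without control replicate 1 of stage 45, with 0.0705, 0.096 and 0.181. Skeletal muscle (0.176, adjusted p = 0.000599) lost it without control replicate 2 (0.725) or thioridazine replicate 3 (0.137) of stage 45 and without control replicate 2 (0.209) or thioridazine replicate 2 (0.0956) of stage 47. Neurons (0.083, adjusted p = 0.0255) lost it without control replicate 1 (0.524) or thioridazine replicate 3 (0.917) of stage 45 and, at stage 47, without control replicate 1 (0.226) or 2 (0.0919) or thioridazine replicate 2 (0.197) or 3 (0.264).

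Pigment cell transcripts were higher after thioridazine at both stages, by a mean of 0.42 on the log2 scale in the 6 pairs of the same replicate number (SD 0.08, higher in 6 of 6). Of the 32 assignments of treatment within pairs 1, the real one, gave a shift of 0.425 and the highest other 0.313. With 38 lists 6 reached that smallest exact p of 0.0312 where 1.19 would be expected. The pattern was picked from these same data, and the assignments take pairs of different stages as independent. This test alone therefore does not exclude chance. More eye tissue in the treated heads is argued against at stage 45. There the pigment shift lay 0.46 (SE 0.129, from 3 pairs) above that of photoreceptor and retinal pigment epithelium genes. An SE from 3 pairs is itself uncertain, so the argument is weak. The 10 retinal pigment epithelium genes had a median log2 fold change of -0.006 at stage 45, 4 of them higher. The median of the pigment list was 0.316. The direction of the photoreceptor list at stage 45 turned without the low-liver libraries (adjusted p = 0.00167). More eye tissue fits at stage 47, where the pigment shift was only 0.092 (SE 0.209) above that of the same list. That small gap rests on pair 2, where the photoreceptor list shifted by 0.651 and the pigment list by 0.343. In pairs 1 and 3 of stage 47 the pigment shifts were 0.435 and 0.515, against 0.249 and 0.116 for the photoreceptor list. The 10 retinal pigment epithelium genes alone had a median log2 fold change of 0.464 at stage 47. That lay above the 0.336 of the pigment list and goes with more eye tissue there. A smaller share of muscle and nerve would raise all other tissues alike. Over both stages together the pigment shift was 0.198 (SE 0.065) above the highest of 7 other lists, myeloid cells (0.227). Lens genes lay at -0.114, a mean of opposite shifts at the stages. At stage 47 alone the mean log2 fold change was 0.439 for pigment, 0.326 for photoreceptor, 0.295 for lens and 0.271 for myeloid genes. It was 0.037 for epidermis, 0.016 for fibrous matrix, 0.005 for cartilage and -0.158 for red blood cells. A drug effect on pigment cells may underlie the pattern, as a hypothesis found and tested on the same data, while more eye tissue at stage 47 and differences in clutch or in how the malformed tadpoles were picked stay open.

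Lens transcripts were lower after thioridazine at stage 45 and not at stage 47. Of the 32 assignments within pairs 1, the real one, gave a difference of 0.819 between the stages and the highest other 0.789. Over 38 lists 1.19 would be expected to reach this by chance and 2 did, lens and xenobiotic metabolism. As the pattern was picked from these same data, chance is not excluded. Reads shared between crystallin copies do not account for it alone, since the 14 lens genes that are no crystallins had a median of -0.427 at stage 45, 13 of them lower. Whether treated heads were later along the stage change cannot be told apart from chance, as 2 of the 20 assignments of labels at stage 45 gave a correlation with the stage effect as large as the real 0.328, the highest other being 0.353. Those assignments disregard the pairing by replicate number. The summed lens level was 1242 CPM at stage 45 and 1431 CPM at stage 47 in treated heads. In controls it was 2170 and 1116 CPM, so the difference closed mainly as controls fell. A drug effect on the lens at stage 45 is a hypothesis that was not tested, and a shift in developmental timing stays open too.

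Liver transcripts were lower after thioridazine at stage 47. Among the 10 splits of the 6 libraries 1, the real one, gave a difference of 1947 CPM in the summed level and the highest other 1848, and 10 splits are too few for a share under 0.05. A varying amount of liver tissue between libraries would make liver genes vary together. Their deviations from group means had a mean correlation of 0.63, where random genes gave -0.001. The correlation that camera estimated was 0.84 for ribosomal protein genes and 0.592 for respiratory chain genes. The value for liver thus cannot tell a varying amount of tissue from genes that vary together for another reason. Whether the liver content of the heads differed, and if so by dissection or by treatment, stays open.

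For the counts of called genes the splits of 6 libraries into 3 and 3 are too few for a share under 0.05. At stage 45 the real count was 0 and the highest other 0, so 10 of 10 splits gave as many, which a real count of 0 fixes in advance. At stage 47 it was 20 and the highest other 0 (1 of 10 splits). The real split parts all 3 pairs, as do 3 of the other splits, and 6 part 1 pair, with 0 genes each. Between stages it was 1689 in controls and 1314 in treated heads, with 0 and 2 as the highest others (1 of 10 splits each). With the block within each stage the real counts were 268 and 171 at stages 45 and 47, and the highest others 0 and 3 (1 of 4 assignments each, too few for a share under 0.05). Averaged over both stages with that block, 1 of 32 assignments, the real one, gave 599 genes and the highest other 144. That is the smallest share 32 assignments can give, for a comparison chosen after the data were seen. It also takes pairs of different stages as independent, so chance is not excluded. For the difference between stages the real count was 0 genes and the highest of the other drawn assignments 3. All 30 of 30 must reach a count of 0, so that share says nothing about chance.

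Counts of lists with the preset correlation were high in other splits too. At stage 45, 14 lists passed and 6 of 10 splits gave as many, up to 18. At stage 47, 22 passed in the real split, the highest of the 10, and the highest other gave 18 (1 of 10 splits). Among splits that part all 3 pairs the highest others were 18 at both stages, and among those that part 1 pair 15 and 18. Between stages 24 passed in controls (1 of 10 splits, highest other 20) and 15 in treated heads (5 of 10 splits, highest other 18). For the difference between stages 25 of 30 assignments gave at least the real 11 lists, up to 24, so chance is not excluded for that count.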

How the results depend on the processing

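The block within each stage, the fit without the 3 libraries of lowest liver level (control replicate 1 and thioridazine replicate 3 of stage 45, thioridazine replicate 2 of stage 47) and the lens list with numbered copies were chosen after the results were seen. Other than where stated, the cause of a change was not tested.

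At stage 45 the count of 0 genes became 76 with DESeq2, 16 with the replicate block and 268 with the block within each stage, and 0 to 9 without 1 library. It stayed at 0 with RLE or upper-quartile scaling, no filter, 1 CPM in 3 libraries, summed homeologs, only the groups compared and the low-liver libraries left out. At stage 47 the 20 genes became 68 with DESeq2, 51 with the replicate block, 171 with the block within each stage, 7 without low-liver libraries and 0 to 24 without 1 library, fewer samples being part of the cause. It was 18 to 27 under the other alternatives without a fold threshold. The difference between stages gave 4 genes with DESeq2, 27 with the block within each stage, and 0 without any 1 library.

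Between stages in controls the 1689 genes became 660 with only the groups compared, 3068 with the replicate block, 527 without low-liver libraries, 245 at 2-fold and 429 to 1768 without 1 library. In treated heads the 1314 became 1975 with DESeq2, 2704 with the block, 125 without low-liver libraries, 187 at 2-fold and 392 to 1738 without 1 library.

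With an estimated correlation 2 lists passed in place of 14 at stage 45 and 2 in place of 22 at stage 47, and 0 in place of 24, 15 and 11 for the stage contrasts and the difference between stages. Fry called 2, 2, 15, 12 and 0. Without 1 library the list counts ranged from 14 to 22, 15 to 23, 20 to 24, 13 to 19 and 8 to 17.

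The correlation of 0.15 between the treatment effects of the 2 stages was 0.023 with DESeq2, 0.019 without low-liver libraries and 0.006 to 0.242 without 1 library. The correlation with the stage effect ranged from 0.298 to 0.589 at stage 45 and from 0.142 to 0.46 at stage 47 without 1 library, and was 0.206 at stage 47 without low-liver libraries.

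Directions reversed without low-liver libraries for photoreceptors (adjusted p = 0.00167) and ribosomal proteins (0.138) at stage 45, and for the difference between stages in neurons (0.105) and ribosomal proteins (0.0213). Directions also reversed without some single library, with adjusted p over these from 7.27e-06 to 0.591 for the respiratory chain, 0.00205 to 0.526 for cilia and 4.44e-25 to 0.366 for ribosomal proteins at stage 45. For ribosomal proteins they ranged from 1.03e-08 to 0.301 at stage 47 and from 8.65e-15 to 0.654 for the difference, and for liver from 1.07e-08 to 0.782 between stages in treated heads.

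For the named genes, alternatives set beforehand kept direction and side of the threshold in 2317 cases, passed newly in 52, lost the call in 95 and reversed 0. For lists these were 2725, 100, 209 and 6. No scaling moved the median of all genes by over 0.04 on the log2 scale. With numbered crystallin copies added, the lens list at stage 45 had an adjusted p of 8.94e-48, and 0.117 with an estimated correlation. At this depth and spread the gene test recovered 30% of simulated 1.5-fold and 60% of 2-fold changes at stage 47, so smaller changes were mostly not detectable. The simulated data held no pairing between samples, so recovery in the real data, which do, was not measured.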

Other observations

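The genes and lists in this part were chosen after the results were seen.

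With the block within each stage, calls fell on several members of the same gene lists. At stage 45, where the fit without a block called no gene, these were 9 pigment genes, all higher, among them xdh.S, gpr143.S, pmel.S and slc45a2.L, and 10 skeletal muscle genes, all lower, among them tnni1.S, tpm2.L, ckm.L and mybpc1.S. Another 7 were neuronal genes, all lower, among them the glutamate receptor genes gria2.S and grin1.L and the kinase genes camk2a.S and camk2b.L. At stage 47 these were 15 photoreceptor genes, all higher, among them gnat2.S, opn1lw.L, pde6h.L and guca1c.S of cones, and 8 pigment genes, all higher. Of these the fit without a block also called grk7.L, dct.L, tyrp1.L and pmel.L.

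The numbered gamma-crystallin copies, which the lens list left out, moved with it. Of 58 copies 57 were lower at stage 45 (median -0.85) and 45 were higher at stage 47 (median 0.11), and the difference between stages was above 0 in 58 of 58 (median 0.94). Near-identical copies share reads, so these are not 58 independent genes.

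Over the 6 pairs of the same replicate number, lysosome genes had a mean shift of 0.16, metalloproteinases of 0.13, signalling pathway genes of 0.06 and neurons of -0.17, each with the same sign in 6 of 6 pairs (exact p = 0.0312, the smallest that 32 assignments can give). Myeloid genes (0.23) and skeletal muscle genes (-0.21) had an exact p of 0.0625.

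The agreement of the treatment effects of both stages was compared with other assignments of the treatment labels. The highest correlation in any other assignment was 0.473 over all assignments and 0.414 within pairs, above the real 0.144.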
